A study of Mus musculus with 108 samples.

How the data were processed

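The data were processed values of Affymetrix Mouse Genome 430 2.0 arrays from the optic nerve head (ONH) and the retina of DBA/2J mice and of their D2-Gpnmb+ controls. According to the labels, 20 ng of total RNA per sample was amplified and labelled as biotin cDNA with a NuGEN Ovation kit, and 2.5 µg was hybridized. The submitters' notes name GCOS for the scanner values and RMA in the affy package for normalization, without versions. The deposited values are per the labels log2 RMA signals, and they ran from 1.81 to 14.31 over 45101 probe sets and 108 arrays. Array medians lay between 4.88 and 5.23 in the ONH and between 5.02 and 5.16 in the retina. The labels leave open whether both tissues were normalized together, so each tissue was analysed apart and tissues were compared only through effects. The number of arrays, 60 for the ONH and 48 for the retina, limits the precision.

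The number in each description recurs for a left and a right eye and was taken as the mouse. By that reading there were 50 mice and 60 eyes, 48 eyes gave both tissues, and 10 mice gave both eyes to the ONH set and 7 to the retina set. Eyes of the same mouse were not treated as independent.

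Of the probe sets, 34958 belonged to exactly 1 gene, 932 to several genes and 9211 to no gene in the gene table used here. Probe sets with several genes or none were left out because no single gene could be named for them. This removed every probe set of C3 and C4b. The remaining probe sets covered 18194 genes, and 34754 were matched by Entrez number. Each gene was represented by its probe set with the highest mean over all arrays of the tissue. A gene was tested when that probe set reached a log2 value of 5 on at least 8 arrays, the size of the smallest group, which left 12100 genes in the ONH, 11322 in the retina and 10763 in the comparison between tissues.

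Each tissue was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with all groups in 1 model and the mouse as a random block. The within-mouse correlation from duplicateCorrelation was 0.0774 in the ONH and 0.0366 in the retina. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called changed at an adjusted p under 0.05. No or early eyes were compared as the equal-weight mean of sets 1 and 2. For the comparison between tissues, the ONH value minus the retina value of the same eye was fitted in the same way, with a within-mouse correlation of 0.0987.

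Before the data were examined, 34 gene lists with 552 members were fixed, of which 507 members were on the array, 3 of them under an older symbol. The immune and glial lists were complement, reactive astrocyte and Müller glia, astrocyte identity, Müller glia, microglia and macrophage, monocyte and infiltrating leukocyte, MHC and antigen presentation, interferon response, and leukocyte adhesion and transendothelial migration. Lists for signalling and matrix were the endothelin system, extracellular matrix, TGF-beta and BMP signalling, and neurotrophin and growth factors. Neuronal lists were retinal ganglion cell, axon injury and stress response of neurons, photoreceptor, bipolar cell, and amacrine and horizontal cell. Other cell types were covered by the lists oligodendrocyte and myelin, oligodendrocyte precursor, retinal pigment epithelium, melanocyte and pigment, lens crystallin, endothelial cell, pericyte and smooth muscle, scleral and meningeal fibroblast and cartilage, skeletal muscle, and erythrocyte. The remaining lists were cell cycle, cholesterol synthesis, hypoxia and glycolysis, immediate early and glucocorticoid, heat shock and unfolded protein response, and mitochondrial respiratory chain. Lists were tested against all other genes with cameraPR in limma on the moderated statistics, with a preset correlation between genes of 0.01 and again with a correlation estimated from the residuals of each list. The p-values were adjusted over the lists of a comparison. Skeletal muscle and erythrocyte had too few measured members for such a test, and the retina had enough for 28 lists.

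Genes were named by a rule fixed before the data were examined. Named were the 8 largest rises and the 8 largest falls of each comparison among changed genes, up to 4 changed members of each list by size or, where none changed, up to 2 with the smallest p, and a set of genes fixed in advance. Among these were Gpnmb, Gfap, C1qa, C3, C4b, Edn2, Ednrb, Lcn2, Serpina3n, Timp1, Pou4f1, Nefl, Sncg, Mbp and Rpe65.

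The fits were repeated with array weights, without the filter, with the mean of all probe sets of a gene, without the mouse block, with the replicate number of the title as a block, with only the groups compared, with the means of the photoreceptor and retinal pigment epithelium lists as covariates, with the range of mouse numbers as a factor, with only the mice whose number starts with 113, and after another quantile normalization within each tissue. Where only the groups compared were fitted and too few mice gave both eyes, the mouse correlation could not be estimated and the block was dropped. After the first results, fits were added without the ONH array of severe replicate 6, without both eyes of 1 severe mouse, without no or early 2 replicate 11, without all 9 doubted arrays, with the Gapdh 3 prime minus 5 prime signal as covariate, and with the medians of the bacterial control probe sets as covariates. An array was doubted when its Gapdh 3 prime minus 5 prime difference was at least 1.9, when it came from the mouse with low Xist, or when its photoreceptor list mean stood apart from its group. For every comparison the group labels of the arrays compared were also shuffled, which gave 100 splits with the real one, and the changed genes were counted again for each.

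The scripts were tested on simulated data with the group sizes and mouse structure of the arrays. Log2 changes of 0.5, 1 and 2 were given to 67, 67 and 66 genes. In the ONH comparison of severe eyes with controls 68.7%, 92.5% and 100% of them were recovered, and 12 of 11880 unchanged genes were called. For the retina 91% were recovered at a log2 change of 0.5 and 100% at both larger sizes, with 15 of 11102 unchanged genes called. Between tissues the shares were 67.2%, 94% and 98.5%, with 11 of 10543 unchanged genes called. The fitted mouse correlation was 0.105, 0.109 and 0.114 where 0.1 had been set.

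The submitters' clustering tables held 570 probe sets over 50 eyes for the ONH and 599 over 48 eyes for the retina. Their values matched the deposited log2 table within 5e-07, and they were used for that comparison only, because the selection of their probe sets was made on the same samples and is not described in the labels.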

Results

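Gene expression was measured with Affymetrix arrays in the optic nerve head (ONH) and the retina of female DBA/2J mice, which develop an inherited pigmentary glaucoma, and of D2-Gpnmb+ controls, which carry a working Gpnmb gene on the same background and do not. The values were log2 signals per probe set. According to the labels the ONH punch also holds some central retina, choroid and sclera. Eyes were sorted by optic nerve damage into no or early, moderate and severe glaucoma, and the no or early eyes came in sets 1 and 2, a division that the labels do not explain. Mice were 10.5 months old, except for a preglaucoma group of DBA/2J mice aged 4.5 months that was measured in the ONH only. The ONH groups held 10 control, 10 preglaucoma, 10 no or early 1, 11 no or early 2, 9 moderate and 10 severe arrays, from 7, 7, 10, 10, 9 and 9 mice. For the retina there were 10 control, 10 no or early 1, 10 no or early 2, 8 moderate and 10 severe arrays, from 7, 10, 9, 8 and 9 mice. The number of arrays limits the precision of every value. Eyes with the same number were taken as 1 mouse.

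Changes are given as log2 differences ± standard error (SE), levels as mean log2 ± standard deviation (SD), and adjusted p-values come from limma over all genes of a comparison. A gene is said to rise, fall or change only when its adjusted p was under 0.05. For gene lists, the adjusted p refers to a test of the list against all other genes with a preset correlation between genes, and a p-value with an estimated correlation is given beside it where the first was under 0.05. A rise from or fall to a group mean under log2 5, the level used to filter genes, is taken as a lower bound, and only the direction is read where both means lie under it. A range count is the number of changed genes in the mouse number range of all controls. That leaves few arrays, severe ones mostly of the low-Xist mouse. Comparisons, lists, naming rule and thresholds were fixed before the data were examined. Of 540 list tests, 196 passed with the preset correlation and 38 with an estimated one.

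Gpnmb, the gene that separates the strains, was read first because it checks the group labels. It codes for a glycoprotein of pigment granules and phagocytic cells. In the ONH its level was 9.23 ± 0.434 in controls (n = 10) and 6.93 ± 0.499 in no or early 1 eyes (n = 10), and in the retina it was 7.65 ± 0.199 in controls (n = 10) and 5.80 ± 0.286 in no or early 1 eyes (n = 10). All other DBA/2J groups had Gpnmb means between 6.65 and 6.93 in the ONH and between 5.41 and 5.62 in the retina. The fall in no or early eyes against controls was 2.32 ± 0.154 in the ONH and 1.98 ± 0.13 in the retina (adjusted p = 3.06e-18 and adjusted p = 1.49e-15).

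**Figure D1:**
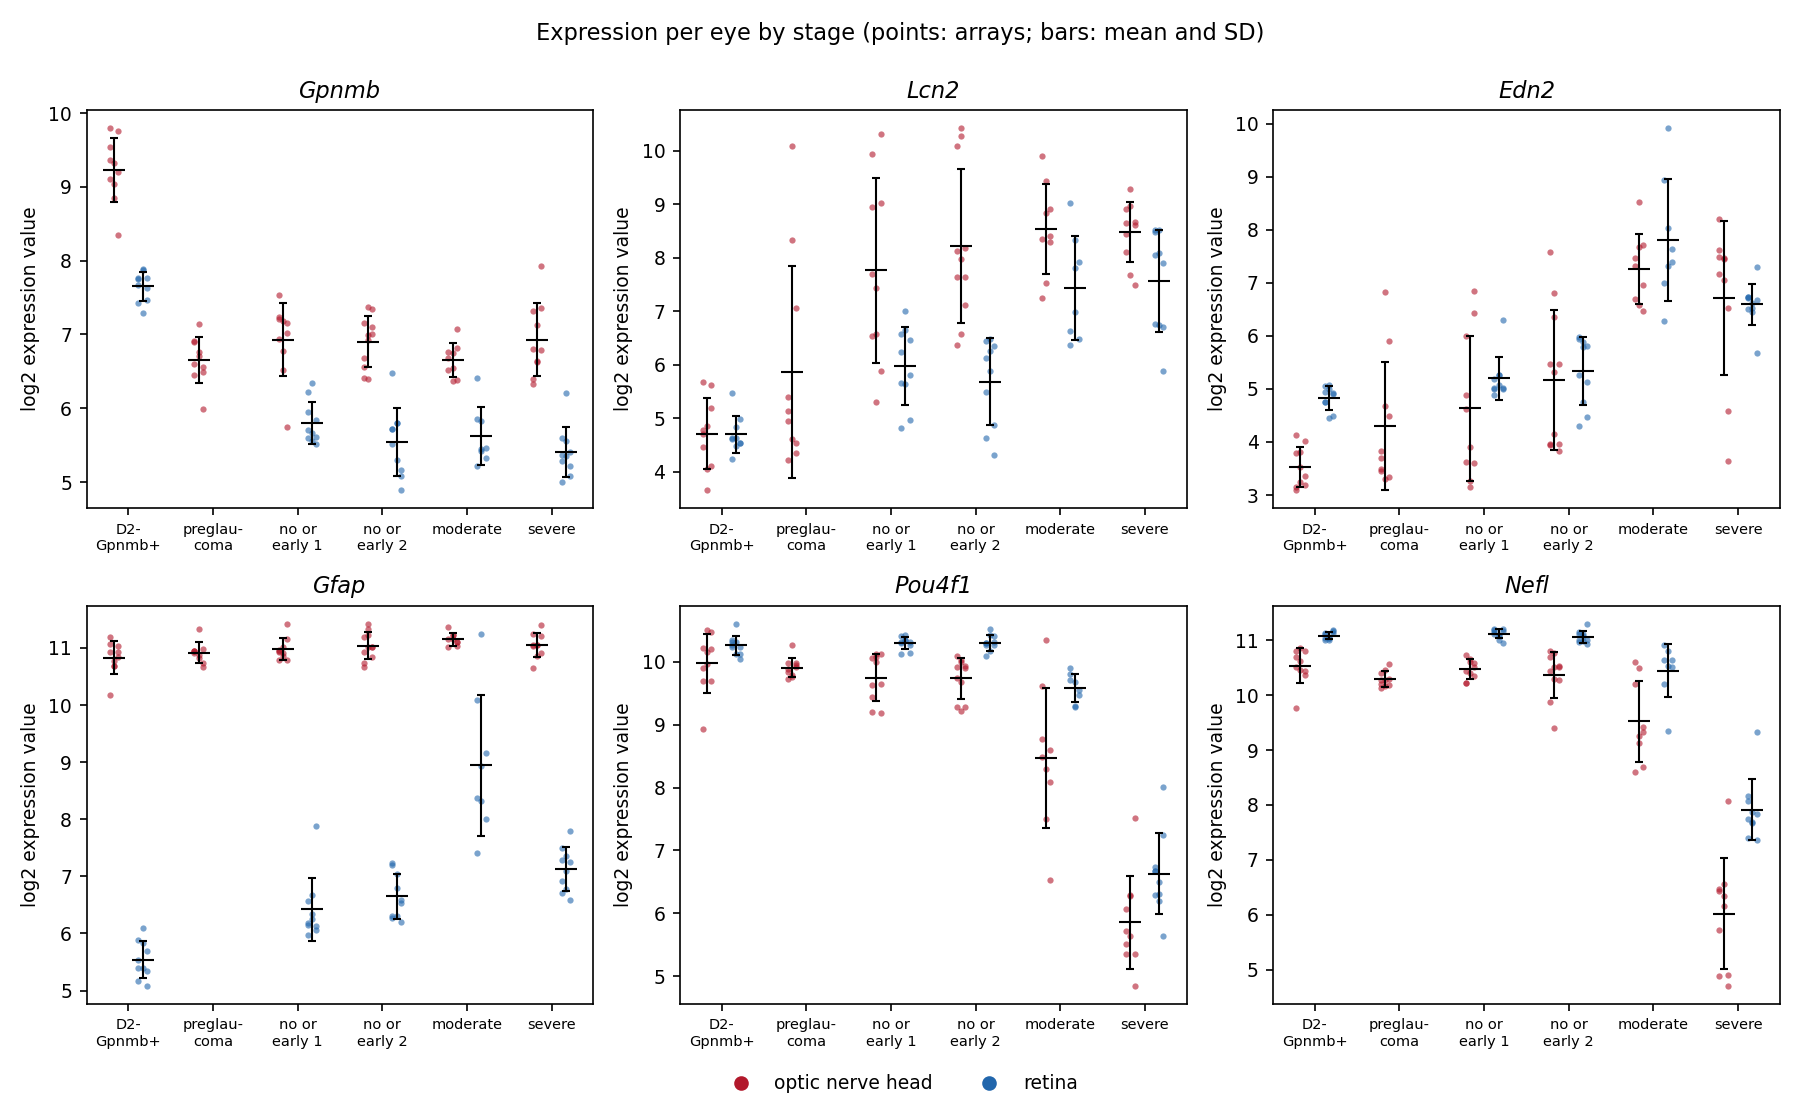
Log2 signal of Gpnmb, Lcn2, Edn2, Gfap, Pou4f1 and Nefl on each array, by group from controls to severe glaucoma, with ONH arrays in red, retina arrays in blue, and bars for mean ± SD. Mean Lcn2 in the ONH was 4.71 in controls and 7.76 in no or early 1 eyes, while Pou4f1 in the retina stood at 10.26 in controls and 6.63 in severe eyes. Gpnmb is shown by a different probe set in each tissue.

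The ONH of DBA/2J eyes with no or early nerve damage was set against controls of the same age but other genotype. In these 21 arrays 265 genes rose and 81 fell of 12100 tested, against 10 control arrays (range count 91). The largest rise was in Lcn2, an iron-binding acute-phase protein, at 3.28 ± 0.507 (adjusted p = 1.06e-05). Most microglia list genes rose, as in preglaucoma ONH, and no ganglion cell list gene changed. The largest falls were in pigment cell genes such as Pmel, a structural protein of melanosomes, which fell by 3.58 ± 0.19 (adjusted p = 4.41e-22).

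Of the changed genes, 31 rose and 16 fell at least 2-fold. Beside Lcn2, large rises were in the acute-phase genes Orm1 (2.56 ± 0.273) and Saa3 (1.77 ± 0.359), the protease inhibitor Timp1 (2.38 ± 0.3, adjusted p = 6.17e-08), the interleukin antagonist Il1rn (1.89 ± 0.229), and the neuropeptide Npy (1.58 ± 0.178). Serpina3n (1.33 ± 0.201, adjusted p = 6.69e-06), a protease inhibitor of reactive astrocytes, rose too. Other large falls were in the melanosome genes Tyrp1 (−3.49 ± 0.2), Mlana (−3.25 ± 0.186) and Dct (−2.28 ± 0.151), the pigment cell regulator Pax3 (−2.38 ± 0.178) and the ion channel Trpm1 (−2.28 ± 0.233). Gfap, an astrocyte filament gene that was already near 11 in the control ONH, did not pass (0.18 ± 0.0833, adjusted p = 0.279). Nor did the endothelin gene Edn2 (1.37 ± 0.436, adjusted p = 0.0727), the complement gene C1qa (0.40 ± 0.182, adjusted p = 0.266) or the ganglion cell genes Pou4f1 (−0.23 ± 0.227, adjusted p = 0.673), Nefl (−0.11 ± 0.213, adjusted p = 0.855) and Sncg (−0.01 ± 0.136, adjusted p = 0.976). With array weights Edn2 (1.23, adjusted p = 0.0223) and C1qa (0.43, adjusted p = 0.0354) did pass.

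The microglia and macrophage list stood at 10 higher and 6 not passing (14 higher adjusted over the list alone, median 0.56, adjusted p = 7.32e-18 and adjusted p = 0.0287 with an estimated correlation). Its largest rises were in the lysosomal marker Cd68 (1.11 ± 0.222), the microglial receptors Trem2 (0.90 ± 0.199) and Tyrobp (0.89 ± 0.162) and the oxidase subunit Cyba (0.81 ± 0.169). For reactive astrocyte and Müller glia genes the result was 6 higher and 15 not passing (9 higher adjusted over the list alone, median 0.35, adjusted p = 4.49e-14 and adjusted p = 0.0287 with an estimated correlation), with the adhesion receptor Cd44 (0.62 ± 0.105). Both estimated values moved to 0.0687 when the 9 doubted arrays were left out. The complement list gave 4 higher and 12 not passing (9 higher adjusted over the list alone, median 0.44, adjusted p = 2.2e-08 and adjusted p = 0.0918 with an estimated correlation), with the complement receptors Itgb2 (1.14 ± 0.205) and C3ar1 (0.99 ± 0.211) and the factors Cfb (0.92 ± 0.202) and Cfi (0.82 ± 0.227). Among monocyte and infiltrating leukocyte genes, 3 higher and 10 not passing (6 higher adjusted over the list alone, median 0.67, adjusted p = 2.2e-08 and 0.0795 with an estimated correlation), the calcium binder S100a8 (1.24 ± 0.256) and the integrin Itgax (1.08 ± 0.185) rose. The extracellular matrix list, with the proteoglycan Vcan (1.09 ± 0.244), tenascin C Tnc (0.83 ± 0.188) and fibronectin Fn1 (0.69 ± 0.135), had 10 higher and 24 not passing (19 higher adjusted over the list alone, median 0.31, adjusted p = 6.59e-16 and 0.145 with an estimated correlation). The melanocyte and pigment list had 9 lower and 2 not passing (10 lower adjusted over the list alone, median −1.93, adjusted p = 2.89e-96 and 4.54e-24 with an estimated correlation). Retinal ganglion cell genes gave 19 not passing (median −0.15, adjusted p = 0.108). Changed genes numbered 1392 with array weights, 709 with photoreceptor and pigment epithelium covariates, 648 with only the groups compared and 194 with the mouse number range as a factor. A replicate number block raised the count.

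Whether the ONH of no or early sets 1 and 2 differed was asked next, with 10 and 11 arrays. No gene passed in limma, and 249 of 12100 had an unadjusted p under 0.05. No gene of any list changed either. Of the lists, 13 passed with the preset correlation and none with an estimated one. Photoreceptor genes were relatively higher in set 2 (median 0.38, adjusted p = 0.000139 and adjusted p = 0.559 with an estimated correlation), and the retinal ganglion cell, microglia and reactive glia lists did not pass.

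Moderate ONH was compared with control ONH, with 9 and 10 arrays. In total 1171 genes rose and 1440 fell, 172 and 160 of them at least 2-fold (range count 204). Calcb, which codes for a calcitonin gene-related peptide, rose by 4.61 ± 0.449 and the endothelin gene Edn2 by 3.76 ± 0.519 (adjusted p = 1.47e-11 and adjusted p = 3.18e-07). Most cell cycle genes rose, and most ganglion cell genes fell. Pou4f1, a transcription factor of retinal ganglion cells, fell by 1.49 ± 0.27 (adjusted p = 4.71e-05).

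Other large rises were in Lcn2 (3.84 ± 0.603), Timp1 (3.70 ± 0.357), the midbody gene Cep55 (2.96 ± 0.382), the growth factor Ereg (2.63 ± 0.418) and the mitotic kinase Pbk (2.59 ± 0.263). Large falls were in Pmel (−3.82 ± 0.226), Tyrp1 (−3.69 ± 0.237), Mlana (−3.46 ± 0.221), the receptor Gpr50 (−3.15 ± 0.627), Gpnmb (−2.57 ± 0.183) and the astrocyte enzyme Etnppl (−2.53 ± 0.308). The cytokine Lif (2.44 ± 0.326, adjusted p = 1.48e-07), the pentraxin Ptx3 (2.19 ± 0.379), Serpina3n (1.57 ± 0.239), C1qa (1.01 ± 0.217) and Gfap (0.33 ± 0.0991) rose, and the neurofilament Nefl (−1.0 ± 0.253) and synuclein Sncg (−0.55 ± 0.162) fell. Mbp, a myelin gene (−1.26 ± 0.559, adjusted p = 0.1), and Rpe65, an enzyme of the pigment epithelium (−0.48 ± 0.31, adjusted p = 0.287), did not pass.

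The cell cycle list had 13 higher and 4 not passing (14 higher adjusted over the list alone, median 0.73, adjusted p = 1.12e-12 and adjusted p = 0.0125 with an estimated correlation), with the nucleotide reductase Rrm2 (2.31 ± 0.329), the topoisomerase Top2a (2.22 ± 0.289), the survivin gene Birc5 (2.18 ± 0.332) and the proliferation marker Mki67 (1.56 ± 0.255). For reactive glia the list held 16 higher and 5 not passing (19 higher adjusted over the list alone, median 0.65, adjusted p = 3.92e-15 and adjusted p = 0.0161 with an estimated correlation). Retinal ganglion cell genes had 12 lower and 7 not passing (14 lower adjusted over the list alone, median −0.74, adjusted p = 1.66e-08 and 0.022 with an estimated correlation), with the channel Kcnd2 (−1.48 ± 0.289) and the glutamate transporter Slc17a6 (−1.21 ± 0.249). Amacrine and bipolar list means were also lower (7.89 and 7.85, controls 8.65 and 8.6). Less retina was not tested. The list for axon injury and stress response of neurons gave 5 higher and 10 not passing (the same adjusted over the list alone, median 0.20, adjusted p = 0.000341 and adjusted p = 0.174 with an estimated correlation), with the receptor Tnfrsf12a (1.38 ± 0.269) and the transcription factor Sox11 (1.16 ± 0.245). Complement counted 8 higher and 8 not passing (9 higher adjusted over the list alone, median 0.57, adjusted p = 4.98e-05 and adjusted p = 0.22 with an estimated correlation). Interferon response had 11 higher and 3 not passing (12 higher adjusted over the list alone, median 0.98, adjusted p = 6.23e-07 and adjusted p = 0.22 with an estimated correlation), with the antiviral genes Mx1 (1.54 ± 0.37) and Oas1a (1.43 ± 0.286). Microglia and macrophage genes had 11 higher and 5 not passing (median 0.62, adjusted p = 1.33e-06 and adjusted p = 0.22 with an estimated correlation) and melanocyte and pigment genes 10 lower and 1 not passing (median −1.97, adjusted p = 1.59e-39 and adjusted p = 9.06e-10 with an estimated correlation).

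Within the strain, 9 moderate and 21 no or early ONH arrays were compared. There 345 genes rose and 559 fell, with 49 and 24 at least 2-fold. The count was 1568 with array weights and 522 with the range of mouse numbers as a factor, and the range count was 1. Calcb rose by 4.38 ± 0.386, Edn2 by 2.38 ± 0.445 and Lif by 1.82 ± 0.28 (adjusted p = 3.28e-12, 0.000244 and 1.34e-05). Lcn2 did not pass (0.56 ± 0.518, adjusted p = 0.601). Pou4f1 fell by 1.26 ± 0.232 and Nefl by 0.89 ± 0.218 (adjusted p = 0.000187 and 0.00517).

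The rises also held Ereg (2.34 ± 0.359), Cep55 (2.06 ± 0.329), the hyaluronan synthase Has2 (2.02 ± 0.367), Ptx3 (1.89 ± 0.326), Timp1 (1.32 ± 0.306) and Tnc (1.26 ± 0.192). Large falls were in Etnppl (−2.09 ± 0.264) and the tight junction gene Cldn10 (−1.93 ± 0.236), and the receptor genes Htr1b (−1.42 ± 0.17) and Chrna6 (−1.34 ± 0.229), which ganglion cells express, fell too. The cell cycle list gave 11 higher and 6 not passing (13 higher adjusted over the list alone, median 0.55, adjusted p = 9.04e-16 and adjusted p = 0.00274 with an estimated correlation), with Top2a (1.55 ± 0.249) and Cdk1 (1.21 ± 0.153). Retinal ganglion cell genes had 11 lower and 8 not passing (15 lower adjusted over the list alone, median −0.54, adjusted p = 1.29e-12 and 0.00274 with an estimated correlation). Amacrine and bipolar list means were lower too (7.89 and 7.85, no or early 8.29 and 8.1 or more). The axon injury list had 5 higher and 10 not passing (the same adjusted over the list alone, median 0.14, adjusted p = 2.18e-05 and adjusted p = 0.0861 with an estimated correlation), with Sox11 (1.39 ± 0.21) and the peptidase Ecel1 (0.66 ± 0.112). Reactive glia genes counted 6 higher and 15 not passing (7 higher adjusted over the list alone, median 0.27, adjusted p = 2.59e-07 and adjusted p = 0.198 with an estimated correlation) and microglia and macrophage genes 16 not passing (median −0.02, adjusted p = 0.949).

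Severe ONH, the last stage of nerve damage, was compared with control ONH, with 10 arrays each. Here 1293 genes rose and 1638 fell, of which 124 and 446 at least 2-fold (range count 1471). Retinal ganglion cell genes were among the large falls, the neurofilament gene Nefl by 4.51 ± 0.248, Slc17a6 by 4.63 ± 0.243 and Pou4f1 by 4.11 ± 0.264 (adjusted p = 4.51e-22, adjusted p = 6.11e-23 and adjusted p = 2.72e-19). Pigment cell genes fell as well.

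Calcb rose by 4.74 ± 0.439, Lcn2 by 3.76 ± 0.589, Edn2 by 3.17 ± 0.507 and Timp1 by 2.98 ± 0.348 (adjusted p = 6.39e-13, adjusted p = 1.4e-06, adjusted p = 2.08e-06 and adjusted p = 1.12e-09). Other rises were in Orm1 (2.48 ± 0.318), Tnc (2.11 ± 0.218) and Ptx3 (2.09 ± 0.37). The large falls included the synaptic priming gene Unc13c (−4.33 ± 0.213), the axonal spectrin Sptbn4 (−4.27 ± 0.247), the neurofilament Nefm (−3.92 ± 0.18) and the melanosome genes Tyrp1 (−4.14 ± 0.232), Pmel (−3.75 ± 0.221) and Gpnmb (−2.30 ± 0.179). C1qa (0.70 ± 0.212) and Serpina3n (1.47 ± 0.234) rose and Sncg (−0.89 ± 0.158) fell. Gfap (0.22 ± 0.0968, adjusted p = 0.0926) and Mbp (−0.86 ± 0.547, adjusted p = 0.27) did not pass.

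Retinal ganglion cell genes counted 17 lower and 2 not passing (the same adjusted over the list alone, median −1.73, adjusted p = 1.8e-44 and adjusted p = 2.29e-11 with an estimated correlation). For reactive glia the list had 16 higher and 5 not passing (19 higher adjusted over the list alone, median 0.76, adjusted p = 2.05e-11 and adjusted p = 0.0723 with an estimated correlation). The complement list gave 12 higher, 1 lower and 3 not passing (14 higher and 1 lower adjusted over the list alone, median 0.70, adjusted p = 1.24e-05 and adjusted p = 0.217 with an estimated correlation), with Cfi (1.41 ± 0.263), C3ar1 (1.06 ± 0.245) and C5ar1 (0.93 ± 0.228). Microglia and macrophage genes held 12 higher and 4 not passing (13 higher adjusted over the list alone, median 0.66, adjusted p = 3.22e-06 and adjusted p = 0.255 with an estimated correlation), led by Cd68 (0.97 ± 0.258). Monocyte and infiltrating leukocyte genes had 9 higher and 4 not passing (11 higher adjusted over the list alone, median 0.99, adjusted p = 0.000156 and adjusted p = 0.245 with an estimated correlation), with the chemokines Cxcl10 (1.32 ± 0.448) and Ccl2 (1.19 ± 0.308). Interferon response counted 10 higher and 4 not passing (14 higher adjusted over the list alone, median 0.83, adjusted p = 1.19e-05 and adjusted p = 0.291 with an estimated correlation), with Ifit1 (1.45 ± 0.321) and Rsad2 (1.34 ± 0.401). MHC and antigen presentation had 3 higher and 9 not passing (median 0.23, adjusted p = 0.0715). Leukocyte adhesion and transendothelial migration gave 7 higher, 2 lower and 10 not passing (8 higher and 2 lower adjusted over the list alone, median 0.27, adjusted p = 0.00438 and adjusted p = 0.358 with an estimated correlation), with the selectin Selp (1.36 ± 0.292) higher and the protease Mmp9 (−0.99 ± 0.171) lower. Extracellular matrix genes held 24 higher and 10 not passing (26 higher adjusted over the list alone, median 0.57, adjusted p = 9.11e-14 and adjusted p = 0.217 with an estimated correlation), with Vcan (2.05 ± 0.284). TGF-beta and BMP signalling gave 3 higher and 11 not passing (the same adjusted over the list alone, median 0.13, adjusted p = 0.0269 and adjusted p = 0.432 with an estimated correlation), with the binding protein Ltbp2 (1.27 ± 0.235).

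Among other cell types, astrocyte identity had 5 lower and 5 not passing (the same adjusted over the list alone, median −0.27, adjusted p = 0.0301 and adjusted p = 0.245 with an estimated correlation), with the water channel Aqp4 (−0.72 ± 0.25). The Müller glia list gave 1 higher, 5 lower and 3 not passing (1 higher and 6 lower adjusted over the list alone, median −0.20, adjusted p = 0.0222 and adjusted p = 0.217 with an estimated correlation), with the retinoid carrier Rlbp1 (−1.02 ± 0.147) and the channel Kcnj10 (−0.996 ± 0.201). Oligodendrocyte and myelin genes counted 4 lower and 5 not passing (5 lower adjusted over the list alone, median −1.08, adjusted p = 0.0322 and adjusted p = 0.468 with an estimated correlation), with Mobp (−2.76 ± 1.01). Oligodendrocyte precursor genes had 1 lower and 2 not passing (median −0.12, adjusted p = 0.408). Bipolar cell genes gave 9 lower and 1 not passing (10 lower adjusted over the list alone, median −1.02, adjusted p = 1.16e-06 and 0.217 with an estimated correlation), with Trpm1 (−2.85 ± 0.271), already lower in no or early ONH. Amacrine and horizontal cell genes held 10 lower and 2 not passing (11 lower adjusted over the list alone, median −1.32, adjusted p = 3.11e-08 and 0.217 with an estimated correlation), with the calcium binder Calb2 (−3.09 ± 0.258) and the GABA enzyme Gad1 (−1.73 ± 0.384). The photoreceptor list had 20 not passing (median −0.39, adjusted p = 0.387). Retinal pigment epithelium genes counted 10 lower and 3 not passing (1 higher and 11 lower adjusted over the list alone, median −0.88, adjusted p = 7.77e-05 and 0.248 with an estimated correlation), with the retinoid enzyme Lrat (−1.34 ± 0.281). Melanocyte and pigment genes had 10 lower and 1 not passing (the same adjusted over the list alone, median −2.04, adjusted p = 9.55e-37 and adjusted p = 2.7e-09 with an estimated correlation). Scleral and meningeal fibroblast and cartilage genes held 4 higher and 10 not passing (the same adjusted over the list alone, median 0.25, adjusted p = 0.0185 and adjusted p = 0.368 with an estimated correlation), with the collagen Col1a2 (0.74 ± 0.122). Lens crystallin had 4 not passing (median 0.04, adjusted p = 0.681), endothelial cell 1 higher, 1 lower and 11 not passing (median 0.12, adjusted p = 0.62) and pericyte and smooth muscle 1 higher and 9 not passing (median 0.12, adjusted p = 0.255).

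Of the remaining lists, cell cycle had 2 higher and 15 not passing (1 higher adjusted over the list alone, median 0.35, adjusted p = 0.0125 and adjusted p = 0.387 with an estimated correlation), with the inhibitor Cdkn1a (0.80 ± 0.219). The endothelin list gave 1 higher, 2 lower and 4 not passing (median −0.10, adjusted p = 0.988). Its mean was 0.33, since Edn2 rose and the receptor Ednrb (−0.21 ± 0.069) fell. Axon injury and stress response of neurons counted 3 higher, 2 lower and 10 not passing (median 0.12, adjusted p = 0.508), with the growth cone gene Gap43 (−1.73 ± 0.185) lower and Npy (1.40 ± 0.207) higher. Neurotrophin and growth factors held 3 higher, 2 lower and 4 not passing (median 0.16, adjusted p = 0.681), with Lif (0.98 ± 0.319) higher and Vegfa (−0.50 ± 0.0906) lower. Hypoxia and glycolysis had 1 higher, 4 lower and 8 not passing (median −0.05, adjusted p = 0.227) and immediate early and glucocorticoid genes 1 lower and 13 not passing (median −0.22, adjusted p = 0.255). Heat shock and unfolded protein response held 4 higher and 10 not passing (median 0.08, adjusted p = 0.227). Mitochondrial respiratory chain gave 3 lower and 21 not passing (median −0.10, adjusted p = 0.178) and cholesterol synthesis 1 lower and 13 not passing (median 0.04, adjusted p = 0.495). Too few members of the skeletal muscle and erythrocyte lists were measured for a test, and Pvalb (−2.19 ± 0.192), a calcium binder of fast muscle and of some retinal neurons, fell. Without the eyes of 1 mouse the fall of Ednrb did not pass (−0.14, adjusted p = 0.12). The fall of Rpe65 (−0.92 ± 0.303, adjusted p = 0.0195) turned to a value of 0.32 with the photoreceptor and pigment epithelium list means as covariates (adjusted p = 0.0849). Without severe replicate 6, the array with the lowest photoreceptor list mean (4.286), it was −0.53 and did not pass (adjusted p = 0.07).

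**Figure D2:**
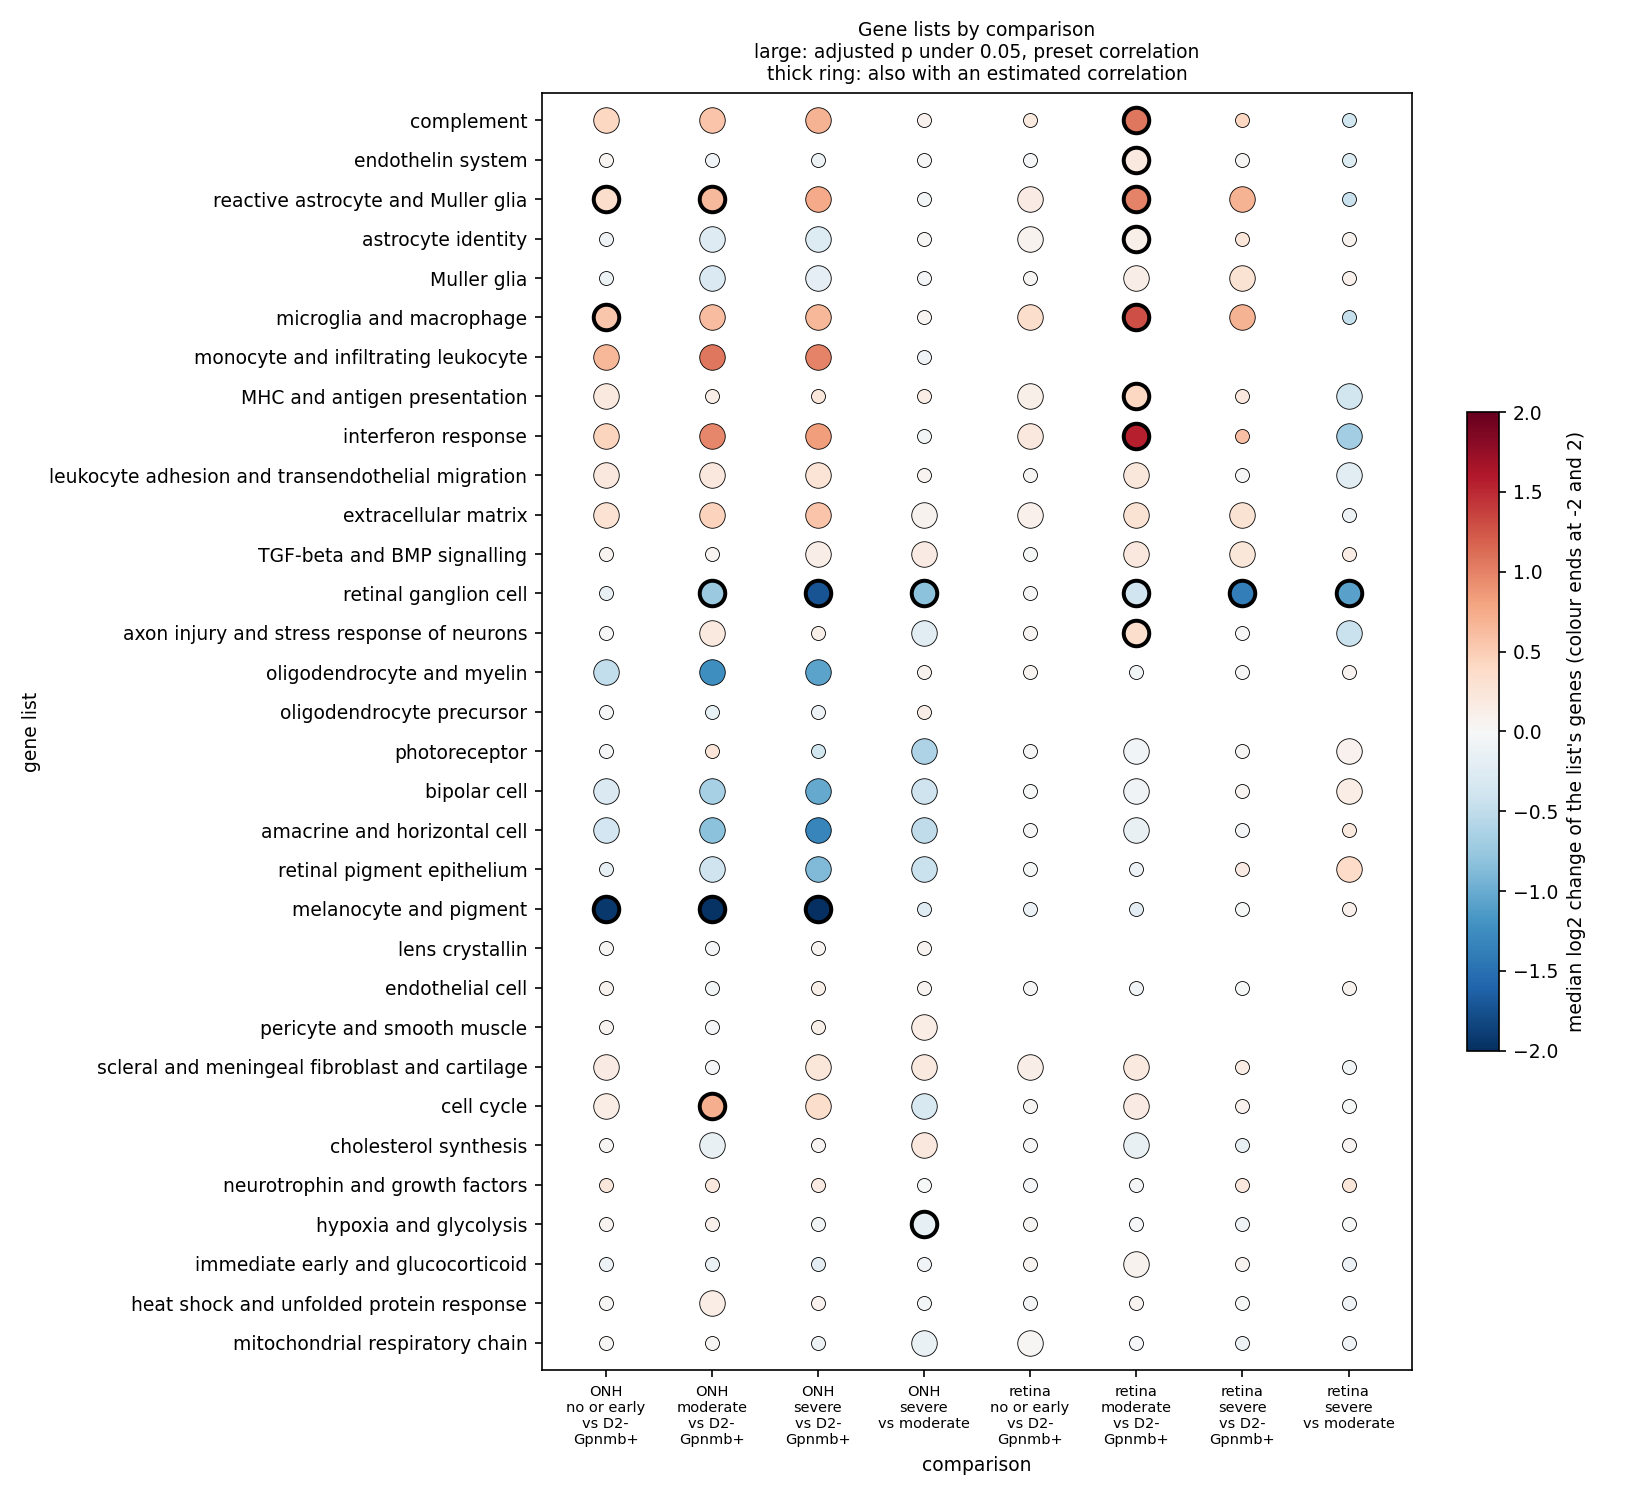
Median log2 change of each gene list (vertical axis) in 8 comparisons (horizontal axis), coloured from −2 to 2, with large points where the adjusted p with the preset correlation was under 0.05 and a thick ring where it also was with an estimated correlation. The retinal ganglion cell list stood at −1.73 in severe ONH and −1.38 in severe retina against controls, and the melanocyte and pigment list at −1.93 in no or early ONH.

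The same 10 severe ONH arrays were set against the 21 no or early arrays, a comparison within the strain. Here 405 genes rose and 1196 fell, with 18 and 238 at least 2-fold (range count 243). Nefl fell by 4.40 ± 0.211 and Pou4f1 by 3.89 ± 0.225 (adjusted p = 6.51e-25 and adjusted p = 2.97e-21). Calcb rose by 4.51 ± 0.374 and Edn2 by 1.8 ± 0.432 (adjusted p = 1.16e-14 and adjusted p = 0.0019). Lcn2, Timp1, Gfap, Serpina3n and C1qa, in that order at 0.48 ± 0.502, 0.59 ± 0.297, 0.04 ± 0.0825, 0.15 ± 0.199 and 0.30 ± 0.18, did not pass.

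Further falls were in Slc17a6 (−4.27 ± 0.207), Unc13c (−4.16 ± 0.181) and the heavy neurofilament Nefh (−4.07 ± 0.251). Rises included the phospholipase Pla2g6 (1.94 ± 0.121) and Ptx3 (1.78 ± 0.316), and the keratin Krt13 and salivary gene Smr2, with means under log2 5. The retinal ganglion cell list had 16 lower and 3 not passing (17 lower adjusted over the list alone, median −1.51, adjusted p = 3.26e-73 and adjusted p = 7.91e-19 with an estimated correlation). Amacrine and horizontal cell genes counted 9 lower and 3 not passing (10 lower adjusted over the list alone, median −0.89, adjusted p = 1.2e-07 and adjusted p = 0.446 with an estimated correlation). Bipolar cell genes gave 5 lower and 5 not passing (10 lower adjusted over the list alone, median −0.57, adjusted p = 0.000589 and adjusted p = 0.463 with an estimated correlation). Reactive glia held 6 higher and 15 not passing (the same adjusted over the list alone, median 0.33, adjusted p = 0.000302 and adjusted p = 0.463 with an estimated correlation) and microglia and macrophage 16 not passing (median −0.02, adjusted p = 0.803).

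Severe ONH was also compared with moderate ONH, with 10 and 9 arrays. In it 154 genes rose and 298 fell, with 11 and 79 at least 2-fold (range count 75). Ganglion cell genes fell further, Nefl by 3.51 ± 0.249 and Pou4f1 by 2.63 ± 0.266 (adjusted p = 6.83e-17 and adjusted p = 5.22e-11). Lif fell by 1.46 ± 0.321 (adjusted p = 0.00254). Edn2 (−0.58 ± 0.51, adjusted p = 0.612), Lcn2 (−0.07 ± 0.593, adjusted p = 0.97) and Timp1 (−0.72 ± 0.351, adjusted p = 0.279) did not pass.

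Rises included Pla2g6 (1.77 ± 0.143), Krt13 (1.70 ± 0.121) and Smr2 (1.62 ± 0.107). Falls were led, beside Nefl, by Nefh (−3.50 ± 0.297), Slc17a6 (−3.41 ± 0.245), Nefm (−3.16 ± 0.181) and Unc13c (−3.10 ± 0.214). The retinal ganglion cell list held 10 lower and 9 not passing (13 lower adjusted over the list alone, median −0.82, adjusted p = 1.8e-45 and adjusted p = 1.26e-11 with an estimated correlation). Cell cycle counted 6 lower and 11 not passing (7 lower adjusted over the list alone, median −0.33, adjusted p = 2.48e-08 and adjusted p = 0.0678 with an estimated correlation), with Rrm2 (−1.74 ± 0.324) and Top2a (−1.73 ± 0.285). For axon injury and stress response the result was 3 lower and 12 not passing (the same adjusted over the list alone, median −0.23, adjusted p = 0.000207 and adjusted p = 0.14 with an estimated correlation), with Sox11 (−1.55 ± 0.241) and Gap43 (−1.45 ± 0.186). Hypoxia and glycolysis genes had 2 lower and 11 not passing (the same adjusted over the list alone, median −0.19, adjusted p = 0.0044 and adjusted p = 0.0254 with an estimated correlation), with the carbonic anhydrase Car9 (−1.11 ± 0.316), and the estimated value moved to 0.174 with the bacterial control covariates. Reactive glia had 21 not passing (median −0.05, adjusted p = 0.865).

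As measured facts beside the severe and preglaucoma comparisons, 10 of 45 bacterial control probe sets changed in severe ONH against the other ONH groups, with a median size of 0.13, and 18 in preglaucoma ONH, with a median size of 0.22. These probe sets detect bacterial transcripts and were chosen after gene values had been seen. None of them changed between moderate and no or early ONH. With the medians of these probe sets as covariates, the number of changed genes was 1306 for severe against moderate ONH and 1976 for preglaucoma against control ONH.

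The preglaucoma comparison set ONH at 4.5 months, before disease, against 10.5-month controls of the other genotype. Age, genotype and mouse number range changed together. With 10 arrays on each side, 268 genes rose and 468 fell, 39 and 9 at least 2-fold. Il1rn rose by 2.17 ± 0.268 and Timp1 by 1.29 ± 0.351 (adjusted p = 4.31e-08 and adjusted p = 0.0171). Lcn2 (1.17 ± 0.594, adjusted p = 0.251), Edn2 (0.79 ± 0.511, adjusted p = 0.403) and Serpina3n (0.57 ± 0.235, adjusted p = 0.145) did not pass.

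Pla2g6 (2.58 ± 0.143), Smr2 (2.57 ± 0.107) and Krt13 (2.25 ± 0.121) rose from control means near background, and Orm1 (1.96 ± 0.32) and Cep55 (1.67 ± 0.377) rose too. Falls were largest in the ubiquitin ligase Mid1 (−2.59 ± 0.27) and in Gpnmb (−2.58 ± 0.18). The microglia and macrophage list had 9 higher and 7 not passing (10 higher adjusted over the list alone, median 0.47, adjusted p = 2.81e-11 and adjusted p = 0.521 with an estimated correlation), with Cd68 (0.99 ± 0.26) and Tyrobp (0.88 ± 0.19). Extracellular matrix genes counted 7 higher and 27 not passing (11 higher adjusted over the list alone, median 0.30, adjusted p = 2.92e-08 and adjusted p = 0.809 with an estimated correlation) and complement genes 2 higher and 14 not passing (median 0.31, adjusted p = 0.00286 and adjusted p = 0.809 with an estimated correlation). Reactive glia stood at 1 higher, 1 lower and 19 not passing (median 0.11, adjusted p = 0.126). After another quantile normalization 365 genes rose and 141 fell of 506.

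Within DBA/2J, 21 no or early and 10 preglaucoma arrays differed in age (10.5 and 4.5 months) and mouse number range. Here 1190 genes rose and 578 fell, 16 and 37 at least 2-fold. Lcn2 rose by 2.11 ± 0.507, Timp1 by 1.09 ± 0.3 and Serpina3n by 0.76 ± 0.201 (adjusted p = 0.00261, adjusted p = 0.00871 and adjusted p = 0.0062). Pigment cell genes fell, Tyrp1 by 3.13 ± 0.2 (adjusted p = 6.47e-19). The microglia and macrophage list did not differ (median 0.04, adjusted p = 0.895).

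Other rises were the steroid dehydrogenase Hsd17b2 (1.54 ± 0.267), the acute-phase gene Saa3 (1.27 ± 0.359) and Tnc (0.98 ± 0.188). Falls also held Pmel (−2.88 ± 0.19), Pla2g6 (−2.65 ± 0.122), Smr2 (−2.51 ± 0.0913) and Krt13 (−2.29 ± 0.103). The melanocyte and pigment list counted 9 lower and 2 not passing (10 lower adjusted over the list alone, median −1.45, adjusted p = 1.47e-42 and adjusted p = 1.56e-10 with an estimated correlation). Reactive glia genes gave 9 higher and 12 not passing (the same adjusted over the list alone, median 0.37, adjusted p = 0.000963 and adjusted p = 0.918 with an estimated correlation). After another quantile normalization 607 genes rose and 774 fell of 1381, so the share of rises depended on the scaling of the arrays. With the bacterial control covariates 25 of 54 passing named genes lost their call.

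In the retina, the same question of no or early eyes against controls was put to 20 and 10 arrays. Of 11322 genes 5 changed in limma and 774 had an unadjusted p under 0.05. The solute carrier Slc25a23 (0.31 ± 0.0596, adjusted p = 0.0152) rose, and Gpnmb (−1.98 ± 0.13, adjusted p = 1.49e-15), Mid1 (−1.58 ± 0.191, adjusted p = 5.91e-07), the deiodinase Dio2 (−0.62 ± 0.115, adjusted p = 0.00729) and the photoreceptor gene Prph2 (−0.37 ± 0.0746, adjusted p = 0.0194) fell. Prph2 lost its call without the doubted arrays. With the range of mouse numbers as a factor 2 of the 5 lost theirs, and with only mice of the range that holds all controls 3 did. Gfap, at 0.995 ± 0.237, and Lcn2, at 1.14 ± 0.296, did not pass (adjusted p = 0.108 and adjusted p = 0.188).

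Edn2 (0.43 ± 0.232, adjusted p = 0.745), Serpina3n (0.64 ± 0.19, adjusted p = 0.348), Pou4f1 (0.04 ± 0.123, adjusted p = 0.962) and Nefl (0.01 ± 0.125, adjusted p = 0.992) did not pass either. Reactive glia counted 15 not passing (5 higher adjusted over the list alone, median 0.16, adjusted p = 3.98e-08 and adjusted p = 0.129 with an estimated correlation). Microglia and macrophage genes had 10 not passing (4 higher adjusted over the list alone, median 0.35, adjusted p = 9.17e-08 and adjusted p = 0.129 with an estimated correlation), with the protease Ctss closest to passing (0.46 ± 0.106, adjusted p = 0.0752). Astrocyte identity genes stood slightly higher (median 0.07, adjusted p = 0.00878 and adjusted p = 0.129 with an estimated correlation), and retinal ganglion cell genes did not differ (median 0.01, adjusted p = 0.408). Between no or early sets 1 and 2, with 10 retina arrays each, no gene passed in limma, 725 had an unadjusted p under 0.05, and no list passed.

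For moderate retina against control retina, the question was what had changed at the middle stage of nerve damage, with 8 and 10 arrays. In this comparison 802 genes rose and 951 fell, 72 and 8 at least 2-fold. The count was 652 with only the groups compared and 715 with the range of mouse numbers as a factor, and the range count was 170. Gfap rose by 3.41 ± 0.29, Edn2 by 2.99 ± 0.283 and Lcn2 by 2.75 ± 0.362 (adjusted p = 6.67e-12, adjusted p = 1.9e-10 and adjusted p = 3.35e-07). Pou4f1 fell by 0.67 ± 0.15 and Nefl by 0.63 ± 0.153 (adjusted p = 0.00135 and adjusted p = 0.00299).

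The rises continued with the chemokine Ccl12 (2.62 ± 0.328), the calcium binder S100a6 (2.36 ± 0.277), the transcription factor Cebpd (2.33 ± 0.254), Serpina3n (2.30 ± 0.232) and the chitinase-like gene Chil1 (2.00 ± 0.206). Falls followed in Gpnmb (−2.03 ± 0.159), Mid1 (−1.73 ± 0.233), the channel and receptor genes Scn4b (−1.35 ± 0.169) and Htr1b (−1.52 ± 0.22), and in Sncg (−0.60 ± 0.0921). Reactive glia counted 12 higher and 3 not passing (14 higher adjusted over the list alone, median 0.99, adjusted p = 5.25e-31 and adjusted p = 8.31e-05 with an estimated correlation). Microglia and macrophage genes gave 9 higher and 1 not passing (the same adjusted over the list alone, median 1.29, adjusted p = 1.03e-19 and adjusted p = 0.00196 with an estimated correlation), with the microglial gene Ly86 (1.58 ± 0.163) and lysozyme Lyz2 (1.43 ± 0.224). For complement the list had 3 higher and 3 not passing (4 higher adjusted over the list alone, median 1.06, adjusted p = 0.000102 and adjusted p = 0.0031 with an estimated correlation), with C1qb (1.60 ± 0.262) and the inhibitor Serping1 (1.55 ± 0.213). Interferon response genes had 7 higher (the same adjusted over the list alone, median 1.55, adjusted p = 5.9e-11 and adjusted p = 0.0106 with an estimated correlation), with Ifit1 (1.86 ± 0.404) and Ifitm3 (1.84 ± 0.247). Endothelin system genes held 2 higher and 2 not passing (the same adjusted over the list alone, median 0.20, adjusted p = 0.00531 and adjusted p = 0.0316 with an estimated correlation), with the receptor Ednrb (0.40 ± 0.111), and the estimated value moved to 0.0589 without the doubted arrays. Astrocyte identity gave 4 higher and 5 not passing (4 higher and 1 lower adjusted over the list alone, median 0.12, adjusted p = 0.00175 and adjusted p = 0.0282 with an estimated correlation), with Aldh1l1 (1.20 ± 0.169). The axon injury list gave 8 higher and 6 not passing (10 higher adjusted over the list alone, median 0.35, adjusted p = 8.81e-13 and adjusted p = 0.0031 with an estimated correlation), with Sox11 (1.64 ± 0.132) and the stress factor Atf3 (1.52 ± 0.187). Retinal ganglion cell genes counted 1 higher, 13 lower and 6 not passing (1 higher and 15 lower adjusted over the list alone, median −0.40, adjusted p = 1.43e-09 and adjusted p = 0.0226 with an estimated correlation).

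Moderate retina was next set against the 20 no or early retinas. Here 866 genes rose and 850 fell, 44 and 3 at least 2-fold (range count 117). Edn2 rose by 2.55 ± 0.248, Gfap by 2.41 ± 0.255 and Lcn2 by 1.61 ± 0.317 (adjusted p = 9.09e-10, adjusted p = 7.75e-09 and adjusted p = 0.000333). The receptor gene Ednrb, through which endothelins act on glia, rose by 0.47 ± 0.0977 (adjusted p = 0.000698). Pou4f1 fell by 0.71 ± 0.132 (adjusted p = 0.00014).

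Rises also included S100a6 (1.99 ± 0.244), Cebpd (1.94 ± 0.223), the cytokine signalling inhibitor Socs3 (1.82 ± 0.321) and Serpina3n (1.66 ± 0.203). With only mice of the number range that holds all controls Socs3 reversed and 77 of 91 passing named genes lost their call. Falls were in Htr1b (−1.36 ± 0.193), Scn4b (−1.12 ± 0.149), Chrnb3 (−0.91 ± 0.111), Nefl (−0.64 ± 0.134) and Sncg (−0.64 ± 0.0808). The axon injury list held 9 higher and 5 not passing (the same adjusted over the list alone, median 0.33, adjusted p = 6.37e-14 and adjusted p = 0.00345 with an estimated correlation), with Sox11 (1.52 ± 0.116) and Atf3 (1.52 ± 0.164). Reactive glia counted 12 higher and 3 not passing (14 higher adjusted over the list alone, median 0.91, adjusted p = 8.81e-25 and adjusted p = 0.000846 with an estimated correlation). For microglia and macrophage genes it was 9 higher and 1 not passing (10 higher adjusted over the list alone, median 0.94, adjusted p = 4.05e-14 and adjusted p = 0.00804 with an estimated correlation), and for retinal ganglion cell genes 1 higher, 15 lower and 4 not passing (1 higher and 18 lower adjusted over the list alone, median −0.40, adjusted p = 4.05e-14 and adjusted p = 0.00406 with an estimated correlation).

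Severe retina against control retina, with 10 arrays each, asked what was changed at the last stage. In total 1561 genes rose and 2066 fell, of which 37 and 72 at least 2-fold (range count 2219). Pou4f1 fell by 3.63 ± 0.142, Slc17a6 by 3.66 ± 0.143 and Nefl by 3.17 ± 0.145 (adjusted p = 1.81e-25, adjusted p = 1.81e-25 and adjusted p = 7.02e-23). Lcn2 rose by 2.86 ± 0.342, Edn2 by 1.75 ± 0.267 and Gfap by 1.59 ± 0.274 (adjusted p = 6.37e-09, adjusted p = 1.36e-06 and adjusted p = 1.3e-05). Amacrine, bipolar and photoreceptor genes mostly did not pass.

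Other rises were in Ccl12 (2.08 ± 0.31), the metalloreductase Steap4 (2.06 ± 0.225), Chil1 (1.88 ± 0.195) and Serpina3n (1.42 ± 0.219). Further falls were in the insulin response gene Trarg1 (−3.73 ± 0.158), the growth factor Nrn1 (−3.40 ± 0.147), Nefm (−3.29 ± 0.162), Htr1b (−2.77 ± 0.208), Sncg (−2.67 ± 0.087), Pvalb (−2.51 ± 0.113) and the surface antigen Thy1 (−1.58 ± 0.076). Ednrb (0.09 ± 0.105, adjusted p = 0.559) and Rpe65 (0.29 ± 0.191, adjusted p = 0.247) did not pass. The retinal ganglion cell list held 18 lower and 2 not passing (the same adjusted over the list alone, median −1.38, adjusted p = 1.53e-86 and adjusted p = 1.35e-17 with an estimated correlation). Reactive glia gave 11 higher and 4 not passing (12 higher adjusted over the list alone, median 0.70, adjusted p = 8.64e-10 and adjusted p = 0.142 with an estimated correlation). Microglia and macrophage genes had 8 higher and 2 not passing (the same adjusted over the list alone, median 0.69, adjusted p = 3.47e-05 and adjusted p = 0.325 with an estimated correlation), with Lyz2 (1.38 ± 0.211) and the protease Ctss (0.97 ± 0.122). Müller glia genes counted 6 higher and 3 not passing (7 higher adjusted over the list alone, median 0.28, adjusted p = 0.00139 and adjusted p = 0.173 with an estimated correlation). Complement gave 3 higher and 3 not passing (median 0.43, adjusted p = 0.151), with Serping1 (1.25 ± 0.201). Amacrine and horizontal cell genes had 1 higher, 2 lower and 9 not passing (median −0.03, adjusted p = 0.689), bipolar cell genes 1 higher and 9 not passing (median 0.04, adjusted p = 0.47) and photoreceptor 2 higher and 18 not passing (median 0.03, adjusted p = 0.215).

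Within the strain, with 10 and 20 arrays, severe retina differed from no or early retina in 2249 higher and 2745 lower genes, 14 and 87 of them at least 2-fold (range count 2386). Pou4f1 fell by 3.67 ± 0.122, Nefl by 3.17 ± 0.125 and Sncg by 2.71 ± 0.075 (adjusted p = 2.18e-28, adjusted p = 1.32e-25 and adjusted p = 1.76e-31). Lcn2 rose by 1.72 ± 0.295, Edn2 by 1.32 ± 0.23 and Gfap by 0.59 ± 0.236 (adjusted p = 7e-06, adjusted p = 9.44e-06 and adjusted p = 0.0387). Gfap reversed with only mice of the number range that holds all controls. The retinal ganglion cell list had 19 lower and 1 not passing (the same adjusted over the list alone, median −1.41, adjusted p = 1.48e-84 and adjusted p = 3.46e-17 with an estimated correlation). Reactive glia genes counted 11 higher and 4 not passing (12 higher adjusted over the list alone, median 0.59, adjusted p = 0.000154 and adjusted p = 0.588 with an estimated correlation). Other rises were in Steap4 (1.37 ± 0.194) and Ccl12 (1.30 ± 0.267), and other falls in Trarg1 (−3.69 ± 0.136), Slc17a6 (−3.67 ± 0.123) and Nrn1 (−3.38 ± 0.127).

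Severe retina was then compared with moderate retina, with 10 and 8 arrays. There 1910 genes rose and 2430 fell, although only 5 and 73 at least 2-fold (range count 443). Gfap fell by 1.82 ± 0.288, Edn2 by 1.23 ± 0.281 and Sox11 by 1.53 ± 0.131 (adjusted p = 3.82e-06, adjusted p = 0.000637 and adjusted p = 1.2e-12). Slc17a6 fell by 3.39 ± 0.15 and Pou4f1 by 2.96 ± 0.149 (adjusted p = 6.88e-23 and adjusted p = 1.16e-20). Lcn2 did not pass (0.11 ± 0.359, adjusted p = 0.832).

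The response genes Serpina3n (−0.88 ± 0.23), Ednrb (−0.32 ± 0.11), Atf3 (−1.17 ± 0.186) and Gap43 (−1.10 ± 0.101) fell as well. Rises were led by A330076H08Rik (1.42 ± 0.207) and the syntaxin Stx19 (1.19 ± 0.169). The axon injury list counted 9 lower and 5 not passing (10 lower adjusted over the list alone, median −0.44, adjusted p = 3.26e-07 and adjusted p = 0.116 with an estimated correlation). Reactive glia had 2 higher, 9 lower and 4 not passing (median −0.45, adjusted p = 0.0733). Retinal ganglion cell genes gave 16 lower and 4 not passing (the same adjusted over the list alone, median −1.09, adjusted p = 2.8e-48 and adjusted p = 9.59e-10 with an estimated correlation). With the mean of all probe sets the fall of Ednrb changed direction. As a measured fact, 23 of 45 bacterial control probe sets were lower in severe retina than in the other retina groups, with a median size of 0.17. With these probe sets as covariates 3159 genes changed against no or early retina and 2628 against moderate retina, where 32 of 106 passing named genes lost their call. With only mice of the number range that holds all controls 70 lost it and 14 reversed.

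**Figure D3:**
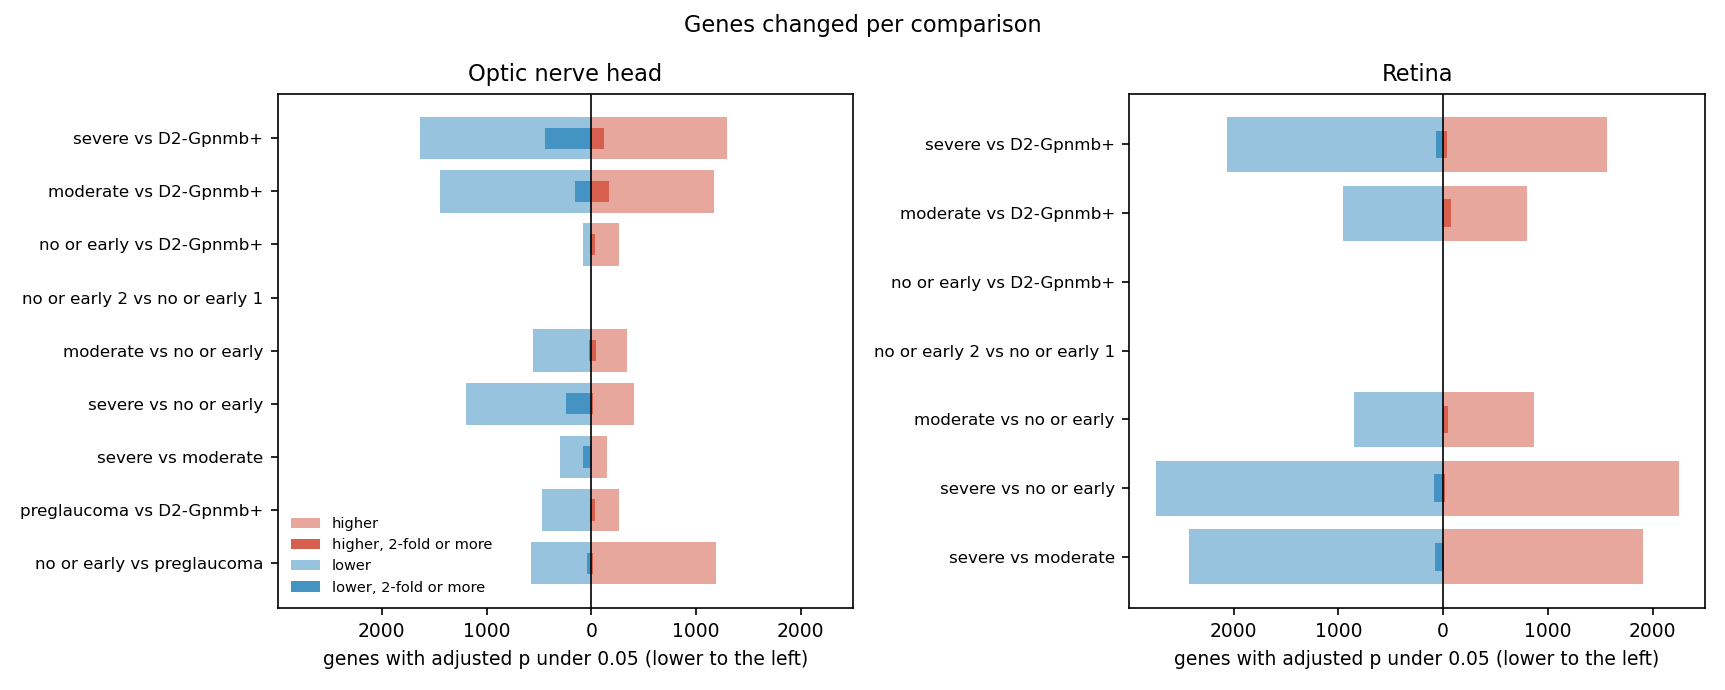
Number of changed genes per comparison, lower to the left and higher to the right, in the ONH and the retina, with all changed genes in pale bars and those changed at least 2-fold in dark bars. Severe retina differed from moderate retina in 4340 genes, of which 5 rose and 73 fell at least 2-fold, while severe ONH differed from control ONH in 2931 genes, with 124 and 446.

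Whether the same genes changed in both tissues was counted over 10789 genes tested in both. For moderate glaucoma against controls 285 higher genes were shared where 62.8 would be shared if the tissues were independent, and 435 lower genes where 115 would be. The 27 others that changed in both did so in opposite directions. For severe glaucoma against controls the shared numbers were 271 against 133 and 591 against 285, with 158 opposite. Within the strain, moderate against no or early eyes shared 99 against 21.7 higher and 220 against 39.7 lower genes, with 9 opposite, and severe against no or early eyes shared 140 against 71.9 and 609 against 276, with 89 opposite. Both tissues came from the same eyes and each pair of comparisons used the same control mice, which raises such overlaps.

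A direct comparison of the tissues asked where the severe effect differed between ONH and retina of the same eye. Against controls the ONH effect was above the retina effect in 774 of 10763 genes and below it in 1324, with 64 and 323 differing at least 2-fold. The difference in effect, ONH minus retina, was −1.36 ± 0.272 for Gfap and −1.35 ± 0.216 for Nefl (adjusted p = 0.000296 and adjusted p = 1.18e-05). For Lcn2 (0.92 ± 0.538, adjusted p = 0.236), Pou4f1 (−0.49 ± 0.235, adjusted p = 0.136) and Serpina3n (0.05 ± 0.306, adjusted p = 0.926) it did not pass. Tenascin C stood out in the ONH, with Tnc (2.30 ± 0.238).

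On the ONH side were also the signalling regulator Rgs4 (2.12 ± 0.168), Nrn1 (1.85 ± 0.152) and Sncg (1.77 ± 0.191), and Sncg fell more in the retina. Below zero stood Tyrp1 (−4.28 ± 0.35), Unc13c (−4.27 ± 0.211), Etnppl (−3.37 ± 0.249), Nefh (−2.11 ± 0.301) and the growth factor Vegfa (−0.82 ± 0.103). The Müller glia list counted 7 lower and 2 not passing (the same adjusted over the list alone, median −0.48, adjusted p = 1.6e-06 and adjusted p = 0.00983 with an estimated correlation). Astrocyte identity gave 5 lower and 4 not passing (the same adjusted over the list alone, median −0.31, adjusted p = 0.00103 and adjusted p = 0.0447 with an estimated correlation). Among melanocyte and pigment genes there were 4 lower and 1 not passing (5 lower adjusted over the list alone, median −2.74, adjusted p = 4.92e-12 and adjusted p = 0.000598 with an estimated correlation). Retinal ganglion cell genes had 6 higher, 10 lower and 3 not passing (median −0.64, adjusted p = 0.915). Reactive glia had 3 higher, 4 lower and 8 not passing (median 0.07, adjusted p = 0.972).

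Against no or early eyes of the same strain, the severe effect was higher in the ONH for 601 genes and lower for 1031, with 34 and 159 at least 2-fold. Nefl stood at −1.21 ± 0.185 and Lcn2 at −1.30 ± 0.461 (adjusted p = 5.3e-06 and adjusted p = 0.0483), the latter because it rose in the severe retina and not in the severe ONH. Pou4f1 (−0.21 ± 0.201, adjusted p = 0.527) and Gfap (−0.54 ± 0.233, adjusted p = 0.115) did not pass. Values were high in Rgs4 (2.06 ± 0.143), Nrn1 (1.96 ± 0.13) and Sncg (1.82 ± 0.163) and low in Unc13c (−4.01 ± 0.181) and Nefh (−2.55 ± 0.257). The receptor Ednrb (−0.32 ± 0.106) was lower on the ONH side. Müller glia counted 6 lower and 3 not passing (the same adjusted over the list alone, median −0.38, adjusted p = 1.98e-05 and adjusted p = 0.0444 with an estimated correlation) and the retinal ganglion cell list 6 higher, 8 lower and 5 not passing (median −0.32, adjusted p = 0.407). Without the 9 doubted arrays 905 genes passed.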

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

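The RNA quality test of severe retina, the test of a graded rise of Pla2g6, Smr2 and Krt13, the test of ganglion cell genes against amacrine cell genes, the test for a male mouse and the added alternative fits were chosen only after the results had been seen. For the other tests the limits were set before the test was run, but the bacterial control probe sets, Xist and the genes read beside it were picked after gene values had been seen. Single arrays far from their group were looked for with Dixon's ratio in 170 groups of named values, and 28 groups had one where about 5% would by chance.

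Low photoreceptor and pigment epithelium list means (4.286 and 6.572) and low Rpe65 (6.698) came together in ONH severe replicate 6, a punch with little retina and pigment epithelium. ONH preglaucoma replicate 5 and ONH moderate replicate 8 had a high Gapdh 3 prime minus 5 prime difference (2.556 and 2.053), as did retina no or early 2 replicate 3 (1.926), a sign of degraded RNA, and preglaucoma replicate 5 also had high Timp1 (8.214) and Gfap (11.33). BioB spike-in controls were low in ONH severe replicate 2 (4.121, nearest other 9.794), the mark of a spike left out or lost. ONH moderate replicate 5 had low C1qa (6.637) and Timp1 (6.789), the values of an eye with less reaction than its group. In the control ONH, replicate 1 was low in Gfap (10.17) and Ednrb (11.43), replicate 10 in Pou4f1 (8.932) and Nefl (9.777) and replicate 8 in Sncg (8.314), as punches with less glia or less retina would be, and Pou4f1 was high in preglaucoma replicate 8 (10.26). In the retina, no or early 1 replicate 3 had high Gfap (7.875) and Edn2 (6.298), the values of a reacting eye. Retina moderate replicate 2 had low Nefl (9.355) and Sncg (7.519), closer to severe, but high Timp1 (6.699, severe mean 3.352). Severe replicate 9 kept Nefl at 9.325. No reason was found for retina Gpnmb in severe replicate 8 (6.201), Edn2 in severe replicate 3 (5.681), Ednrb in no or early 2 replicate 8 (8.792) and severe replicate 6 (7.98), or Pou4f1 in control replicate 2 (10.6).

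Effects that differed between tissues, by limma on the difference of both tissues in the same eye, were counted as 2098 genes for severe against control and 1632 for severe against no or early. Against control they included Gfap (−1.36), Nefl (−1.35), Sncg (1.77) and Rpe65 (−1.21), for which severe replicate 6 lowered the ONH mean. A value of 1.42 for Edn2 cannot be read for size or direction, since its control mean was under log2 5 in both tissues (3.53 and 4.83). Against no or early eyes they included Ednrb (−0.32), Lcn2 (−1.30), Nefl (−1.21) and Sncg (1.82).

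Severe differed from moderate retina in 4340 genes, moderate from no or early in 1716, mostly by little. Of the bacterial control probe sets 51.1% changed in severe retina against all others, above the 25% set for a labelling or hybridisation batch. Against moderate alone it was 11.1%, below that. RNA quality was nearly equal (Gapdh, severe minus moderate −0.069). Of genes changed in severe eyes, 62.5% moved the same way in moderate eyes with separate no or early arrays (limits 55% and 70%, ONH 91.6%). At 2-fold or more it was 74.7%. Some small changes of severe retina may thus come from array processing.

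Pla2g6, Smr2 and Krt13 were higher in severe and preglaucoma ONH than in all other ONH groups, with Pla2g6 at 5.14 ± 0.272 in severe and 5.85 ± 0.171 in preglaucoma eyes (n = 10 each). A shared batch was left open, since 20% of the bacterial control probe sets moved the same way in both groups. A rise graded with stage was not seen, as the largest share already present in moderate eyes was 0.089. Array processing might thus explain these 3 genes. Stage alone does not, since preglaucoma eyes stood above severe eyes. Nor does age alone, equal in severe and no or early eyes. Separate causes were not tested. In retina, severe eyes had the highest mean Smr2 and Krt13 but lowest Pla2g6.

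The fall of ganglion cell genes in severe ONH could reflect less retina in the punch. The change of ganglion cell genes minus that of amacrine cell genes, severe against no or early, was −0.938 (permutation p = 4e-05), so less retina alone is unlikely. With photoreceptor and pigment epithelium list means as covariates the amacrine and horizontal cell list kept 87.4% of its fall (−0.97 to −0.848). Against controls it did not pass in severe retina. The covariates cover other cells, so punch content, cell loss and lower expression stayed open.

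Group labels were shuffled array by array into 100 splits per comparison, the real one included. In the ONH the number of splits with as many changed genes was 1 for severe, moderate and no or early against control (real 2931, 2611 and 346, highest other 787, 2295 and 305), for moderate and severe against no or early (904 and 1601, other 108 and 938), and for preglaucoma against control and no or early against preglaucoma (736 and 1768, other 244 and 2). It was 4 for severe against moderate (452, other 889) and 100 for no or early sets (0, other 0). In the retina it was 1 for severe and moderate against control (3627 and 1753, other 673 and 873), for moderate and severe against no or early (1716 and 4994, other 895 and 2261) and for severe against moderate (4340, other 2162), 2 for no or early against control (5, other 28) and 100 for the sets (0, other 179). For the tissue differences it was 1 both times (other 225 and 1).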

How the results depend on the processing

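Of 232 alternative values of the main counts, 179 stayed within 1.5 times and 53 moved, and the cause was not tested unless named. With array weights counts rose in ONH for no or early against control (1392), moderate and severe against no or early (1568 and 2423), severe against moderate (849), preglaucoma (1747) and no or early against preglaucoma (3210), and in retina for severe (5471) and no or early (70) against control and the sets (4), but moderate against no or early fell to 827. Without the filter, which admits genes of low signal, the ONH gave 3108 for severe against no or early, 1325 for severe against moderate, 3505 for preglaucoma and 5141 for no or early against preglaucoma. The mean of all probe sets gave 1381 for preglaucoma and 13 for no or early retina. Fits of only the groups compared gave 648 and 181 in ONH for no or early against control and severe against moderate, and 652, 25 and 929 in retina for moderate and no or early against control and moderate against no or early. With photoreceptor and pigment epithelium covariates the ONH gave 709 for no or early against control, 1523 for moderate against no or early and 1131 for preglaucoma, and Rpe65, itself a list member, reversed to 0.32. The range of mouse numbers as a factor gave 194 and 522 in ONH for no or early against control and moderate against no or early, and 715, 9 and 1 in retina for moderate and no or early against control and for the sets. Quantile normalization gave 2 for the retina sets.

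Only mice of the number range that holds all controls, which leaves few arrays per group, gave 1471, 204 and 91 in ONH for severe, moderate and no or early against control, 1 and 243 for moderate and severe against no or early and 75 for severe against moderate. In retina they gave 2219, 170, 24, 117, 2386 and 443 in the same order. With them 509 of 897 passing named genes lost their call and 33 reversed, against 10 with the mean of all probe sets and 3 with composition covariates. The remaining alternatives were chosen after seeing the data. Bacterial control covariates gave 1306 and 1976 in ONH for severe against moderate and preglaucoma, and 10, 3159 and 2628 in retina for no or early against control, severe against no or early and severe against moderate. The Gapdh covariate gave 9 for no or early retina. No or early 2 replicate 11 is of doubtful group: it has no retina array, the moderate ONH lacks a replicate 6, and the submitters' clustering table lists it between moderate replicates 5 and 7. Without it counts stayed within 1.5 times. Without the doubted arrays counts were 533 for no or early ONH and 905 for the tissue difference against no or early. List tests passing numbered 196, and 38 with an estimated correlation.

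Replicate numbers recur across groups, and ONH arrays of the same number correlated at a mean of 0.0973 against −0.00896 for others. The replicate block gave 582 for no or early and 1166 for preglaucoma against control in the ONH, and other counts stayed within 1.5 times. As a hint of processing order, replicate number explained 73.4% of the spread of hybridisation controls in the ONH (permutation p = 1e-04) and 11.1% in the retina (permutation p = 0.901).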

Other observations

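Several changes of the ONH were largest at the moderate stage. Cep55, Pbk, Rrm2, Top2a and other cell cycle genes, with Lif and Ereg, rose there above no or early eyes, and Rrm2, Top2a and Lif were lower again in severe eyes. Retinal Gfap, Edn2, Sox11 and Atf3 followed the same course, while Lcn2 stayed high. Against controls Timp1 was already higher in preglaucoma ONH and Lcn2 in no or early ONH, in which the ganglion cell list did not differ.

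Calcb was 3.49 ± 0.409 in control ONH (n = 10) and reached 8.09 ± 1.88 in moderate (n = 9) and 8.21 ± 1.17 in severe eyes (n = 10), while its retina means stayed between 2.84 and 3.19. Its signal in the retina arrays was thus low at every stage.

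Edn2 was asked for a link between tissues in no or early eyes, with both eyes of a mouse averaged (n = 19). ONH and retina Edn2 correlated at r = 0.548 (permutation p = 0.0151, adjusted over 3 relations 0.0453), at 0.363 and 0.762 within sets 1 and 2, but the Spearman correlation was 0.428 (permutation p = 0.0703, adjusted 0.194). ONH Lcn2 and retina Gfap correlated at r = 0.444 (permutation p = 0.0552), or 0.136 without the 2 farthest mice, which decides nothing. The ONH complement list and the retina reactive glia list did not correlate (r = −0.0644, permutation p = 0.793).

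Xist was low on all 4 arrays of 1 severe mouse, with 5.35 and 6.64 in the ONH and 3.85 and 2.89 in the retina. Xist and the genes read beside it were chosen after values were seen. Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, differed by −0.422 in the mean from the 8 other severe mice in the ONH and by −0.444 in the retina, below all of them in both tissues. Genes of the Y chromosome lay within 0.48 of the median, so a male is unlikely, a test added after the first result. The mouse could have a single X chromosome.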
